A study of Drosophila melanogaster with 4 samples.

How the data were processed

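Whole-genome mRNA arrays of male Drosophila melanogaster of the wild-type Canton-S strain were examined. Per the labels, the flies were young adults of 1 to 2 days that were kept in mesh-closed vials inside a bottle holding the vapour of benzene, toluene or formaldehyde for 24 h, or were not exposed. Vapour concentrations are not given in the sources used here. Total RNA was purified on silica columns and 300 ng was amplified and biotin-labelled with an Affymetrix kit that primes from the 3' end, per the labels' protocols. There were 4 arrays, 1 per group: control, benzene, toluene and formaldehyde. Groups were taken from the sample titles.

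The authors deposited 1 table of log2 probe set values for the 4 arrays. The submitters' processing notes name RMA, MAS5 and Affymetrix Expression Console 1.1 with no roles, so which method made the table is not stated. The deposited log2 values ran from 2.43 to 14.5, and their medians over all probe sets were 6.44 (control), 6.42 (benzene), 6.43 (toluene) and 6.44 (formaldehyde). Their shape, with near-equal quantiles across arrays and low values compressed rather than scattered, is that of RMA output. RMA makes the arrays' probe intensities alike in distribution, so it removes any overall difference in RNA amount between groups. It also compresses ratios of dim probe sets.

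The table held 18952 probe sets, of which 183 were array controls. Gene names came from the array's platform annotation: 13646 of the 18769 other probe sets had 1 gene symbol, 402 had several and 4721 had none and are unnamed here. Of the named ones, 13543 matched a gene identifier in RefSeq's Release 6 annotation of the fly genome, and 0 symbols needed updating. That annotation was used for names alone; the table names no genome build, so no coordinates are given. A gene was represented by its probe set with the highest mean over the 4 arrays, which gave 11981 genes, 1094 of them with several probe sets. Other probe sets of a called gene were compared with the chosen one. Of the genes at or past 2-fold, 1 (benzene), 0 (toluene) and 2 (formaldehyde) had another detected probe set, and each of these went the same way by at least 2-fold.

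The values were used as deposited. A gene counted as detected in a comparison when the higher of its 2 values reached that array's median over non-control probe sets (6.43 to 6.46). With 1 array per group there is no replicate, so no test, p-value or standard error could be given; the number of arrays limits the precision of every value. Genes were counted by a size rule, a log2 ratio of at least 1 in either direction (2-fold). A difference between 2 arrays holds the difference between 2 pools of flies, 2 RNA preparations and 2 hybridisations as well as the exposure, and these cannot be told apart. The background of each array was the 95th percentile of its 20 probe sets for unspiked control transcripts (4.64 to 4.88). Where the dimmer value of a named gene lay below it, the ratio was taken against the background and is written as at least so many fold.

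For gene groups, 31 lists were written before the data were examined, 30 of which had a member on the array. Members without a probe set of a single gene symbol dropped out. The heat shock list lost its Hsp70 genes, Hsp22, Hsp23 and Hsp83, and the antimicrobial peptide list DptA, AttA, AttB, AttC and Dro. The alcohol and aldehyde oxidation list lost Adh, Adhr and Aldh, and the DNA damage list rpr and hid. The median log2 ratio of a list's detected members was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. Lists with at least 3 detected members were ranked. A list is called outside the random range when its median lay beyond the middle 95% of the random medians. This describes these arrays, not the conditions. Because list members are regulated together, medians beyond the range are expected more often than for random genes.

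All 3 comparisons with the control use the same control array. Correlations across genes of the log2 ratios, and counts of shared calls, are therefore given beside values from 100 simulations of unchanged arrays sharing a control, in which array noise was drawn from the toluene and benzene differences. Those hold differences between the exposures as well as noise, so the simulation was repeated, after the data were seen, without the 36 genes past 2-fold between these arrays; this also drops any noise of that size. Both simulations gave the control array the same noise as the exposed arrays. Each array was also compared with the other 3 alike, by counting genes at least 2-fold above or below each of them.

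The genes named were set by a rule written before the data were examined. For each exposure against the control, and for toluene against benzene, they are the 10 highest and the 10 lowest detected genes past 2-fold, and the 3 detected members of each list with the largest ratio. In addition 15 genes were to be named whatever their value: Cyp6a2, Cyp6a8, Cyp6g1, GstD1, Hsp70Bb, Hsp68, Hsp22, Fdh, Adh, Aldh, Drs, DptA, TotA, Yp1 and rpr. Of these, 7 (Hsp70Bb, Hsp22, Adh, Aldh, DptA, TotA and rpr) had no probe set with a single gene symbol and were not analysed here. Genes outside the rule are said to be chosen after their values were seen.

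The counting and list steps were tested on simulated data made from the mean of the 4 arrays, with 11981 genes. Normal noise was added, with its size taken from the toluene and benzene differences. All 100 genes simulated at 4-fold and all 100 at 2.83-fold were recovered, and 0 of 7933 unchanged genes were called. The toluene and benzene differences had a robust SD of 0.10, against 0.15 for benzene relative to the control. With noise this small beside 2-fold, these counts check the steps and say little about false calls on the real arrays. Of 100 random lists of 20 genes, 5 fell outside the range, and 20 of 20 lists shifted by 0.2 log2 units were found. Alternatives were other size thresholds, other filters on dim probe sets, quantile, cyclic loess and median scaling, the mean over a gene's probe sets, leaving out probe sets marked as cross-hybridising, and the other exposed arrays as reference. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used, and limma 3.58.1 in R 4.3.3 for cyclic loess; figures were drawn with matplotlib 3.10.9.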

Results

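The data were 4 genome-wide expression arrays of adult male flies, 1 from unexposed flies and 1 each from flies kept for 24 h in benzene, toluene or formaldehyde vapour. These are volatile indoor and industrial pollutants; benzene and toluene are aromatic hydrocarbons that differ by 1 methyl group, and formaldehyde is the simplest aldehyde. The design asks which transcripts differ after each exposure. Values are log2 probe set values, ratios are exposed over control, and no value has a replicate, so no difference was compared with the spread between replicates. Differences are therefore described as higher or lower on 1 array than on another.

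Among named genes, those of the antibacterial response led the benzene array. The diptericin gene DptB was 18.2-fold higher than on the control array (13.10 against 8.92), the peptidoglycan recognition gene PGRP-SB1 was 14.2-fold higher (12.87 against 9.04), and Mtk, which encodes the antimicrobial peptide metchnikowin, was 11.1-fold higher (13.49 against 10.02). The immune-induced gene edin stood at 9.33 and lay below background on the control array, a difference of at least 21.9-fold. Diedel, which encodes a secreted immune regulator, and the stress peptide gene TotC were 4.86-fold and 4.78-fold higher. Then came the cecropin gene CecB (3.32-fold), CG12057 (2.96-fold), the peptidoglycan amidase gene PGRP-LB (2.88-fold) and the mannosidase gene LManVI (2.82-fold). Of 8134 detected genes, 27 were at least 2-fold higher and 8 at least 2-fold lower, and 98.3% lay within 0.5 log2 units of the control.

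The 8 lower genes on the benzene array were of other kinds. CG34040 was lowest, with a log2 ratio of -2.73 and of -1.84 at its other probe set. The lipid-binding gene Npc2f (-1.60) and the cytochrome P450 gene Cyp4e3 (-1.49) followed. Peritrophin-15a, for a chitin-binding protein, was 2.31-fold lower, and the maltase gene Mal-A7 had a log2 ratio of -1.02. CG18404 (-1.19), CG4830 (-1.16) and CG5767 (2.12-fold lower) complete the set.

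**Figure D1:**
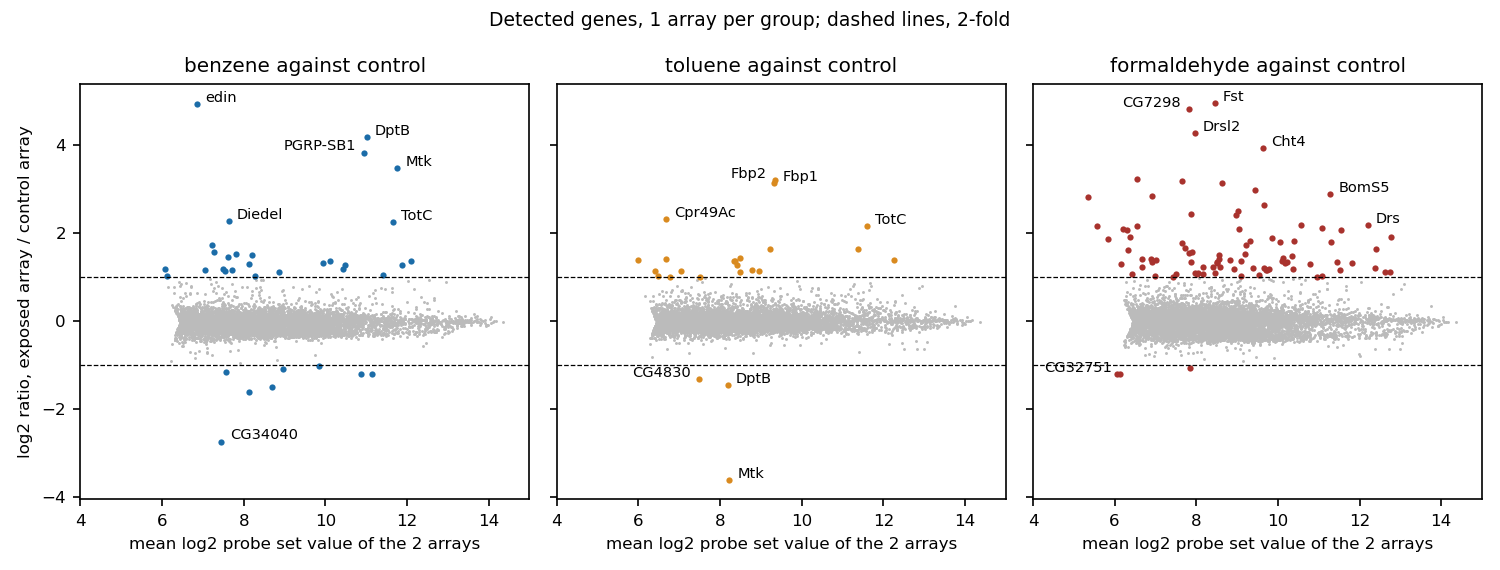
Each point is a detected gene; the x axis is its mean log2 probe set value on the 2 arrays compared and the y axis its log2 ratio of exposed over control, with 1 array per group. Coloured points lie at or past 2-fold (dashed lines): 35 genes for benzene, 23 for toluene and 91 for formaldehyde, with 88 of the last above the control.

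Among the gene lists, 14 of 27 had a benzene median outside the random range, where 1.35 would be expected of random lists. All 6 detected peptidoglycan recognition genes were above 0, with 3 at least 2-fold higher, among them PGRP-SC2 (1.04), and a median log2 ratio of 0.91. The antimicrobial peptide list had 4 of 15 members at least 2-fold higher, 12 above 0 and a median of 0.44. All 4 metallothionein genes, whose products bind metals, were above 0 (median 0.42), led by MtnC (0.50) and MtnB (0.48). Of 38 digestive enzyme genes, 30 were above 0, with LManVI and LManV (1.11) past 2-fold and Mal-A7 lower (median 0.20). Cuticle protein genes had a median of 0.08, with Cpr64Aa at 0.69. In the P450 list, 31 of 57 genes were above 0 and the median of 0.02 lay inside the range.

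Markers of particular tissues also differed on the benzene array. The photoreceptor list was higher, with 9 of 9 members above 0 and a median of 0.26; eys and Galphaq, of the rhabdomere space and the light response, were both at 0.41. Their other, dimmer probe sets gave 0.21, -0.06 and 0.05 for eys and 0.17 and 0.26 for Galphaq. The fat body list had a median of 0.13 and 1 of 7 members past 2-fold (Fbp2, 1.03), and the hemocyte list also 0.13, with eater at 0.31. The testis list was lower, with 19 of 20 members below 0 and a median of -0.22; fzo, a mitochondrial fusion gene of spermatids, was at -0.70. Small shifts beyond the range were lost under at least 1 alternative for glutathione S-transferases (0.05, which turned to below 0 with the filter at the 75th percentile), UDP-glycosyltransferases (0.07), odorant binding proteins (-0.12), accessory gland proteins (-0.08), hemocyte markers and nuclear oxidative phosphorylation (0.02, which turned to below 0 under quantile scaling).

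The toluene array was led by genes of the fat body, the fly's storage and secretory organ. Fbp2 and Fbp1 were 9.18-fold and 8.77-fold higher than on the control array, and Lsp2, for a larval serum protein, was 3.10-fold higher (12.19 against 10.56). TotC was 4.49-fold higher. The cuticle gene Cpr49Ac was 4.99-fold higher, mat 3.10-fold, CG2444 2.69-fold and CG43133 2.68-fold. The odorant binding protein gene Obp99b (2.63-fold) and the lipase gene Lip3 (2.61-fold) were also among the 20 genes at least 2-fold higher of 8140 detected. Only 3 genes were at least 2-fold lower: Mtk by 12.2-fold (6.41 against 10.02), DptB by 2.74-fold and CG4830, with a log2 ratio of -1.32. Within 0.5 log2 units of the control lay 98.2% of the genes. The total of 23 genes fell to 15 when the filter on dim probe sets was raised to the 75th percentile.

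Detoxification genes stood higher as groups on the toluene array, by small amounts. Of 57 detected P450 genes, 46 were above 0 and the median log2 ratio was 0.16; Cyp309a1 (1.11) passed 2-fold, and Cyp6d4 (0.58) and Cyp9b2 (0.57) followed. Of 32 glutathione S-transferase genes, 27 were above 0 (median 0.24), with GstD5 at 1.01, GstD7 at 0.71 and GstD8 at 0.66. All 10 detected genes of alcohol and aldehyde oxidation and one-carbon metabolism were above 0 (median 0.19), led by pug at 0.50. UDP-glycosyltransferase genes had a median of 0.09, which came inside the random range under 3 alternatives; Ugt37A3 was at 0.79. Efflux transporters and their regulators (0.05), antioxidant enzymes (0.07) and heat shock proteins (0.02) stayed inside it. The 9 detected members of the heat shock list held no Hsp70 gene.

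Of the other lists on the toluene array, the fat body list had 4 of 7 members at least 2-fold higher and a median of 1.36. The 4 metallothionein genes had a median of 0.30, and nutrient and insulin response genes one of 0.16, with Lip3 past 2-fold and the storage droplet gene Lsd-1 at 0.76. Digestive enzymes had a median of 0.19, with the amylase-related Amyrel at 0.99, cuticle proteins one of 0.07 (below 0 with no filter), and hemocyte markers one of 0.14; each of these 3 came inside the range under at least 1 alternative. The testis list was lower in all 19 detected members (median -0.14), and the accessory gland list had 21 of 24 members below 0 (median -0.12). Antimicrobial peptides had a median of -0.06, inside the range, and so did peptidoglycan recognition genes at 0.03. In all, 12 of 27 lists lay outside the range.

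The formaldehyde array held the most differences from the control: 88 of 8165 detected genes were at least 2-fold higher and 3 lower, and 96.0% lay within 0.5 log2 units. The cold-responsive gene Fst (Frost) was 30.8-fold higher (10.92 against 5.98) and CG7298 28.1-fold (10.23 against 5.41). The drosomycin-like gene Drsl2 was 19.4-fold higher, and the chitinase gene Cht4 15.2-fold (11.60 against 7.68). CG18563, Acbp6 (an acyl-CoA binding protein), Sid (a stress-induced nuclease) and CG4757 were between 7.94-fold and 9.31-fold higher. BomS5, which encodes a bomanin, a short immune peptide, was 7.37-fold higher, and the lysozyme gene LysX 7.20-fold. The 3 lower genes were CG32751 (-1.20), Amnionless, for an endocytic co-receptor (-1.19), and lectin-33A (-1.07).

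Immune peptide genes had the highest list median on the formaldehyde array. Of 16 detected antimicrobial peptide genes, 8 were at least 2-fold higher and 13 above 0, with a median log2 ratio of 0.98; Drs, which encodes the antifungal peptide drosomycin, was 4.54-fold higher (13.29 against 11.11). In the peptidoglycan recognition list 5 of 6 genes were above 0 and none passed 2-fold (median 0.27; PGRP-SB1, 0.76). All 4 metallothionein genes were above 0 (median 0.54), with MtnD 2.52-fold higher. The fat body list had 3 of 7 members past 2-fold (Fbp1, 2.49; Fbp2, 2.42; Lsp2, 1.02) and a median of 0.58. Photoreceptor genes were above 0 in 9 of 9 cases (median 0.22; Galphaq 0.41, and 0.34 and 0.22 at its other probe sets) and the hemocyte list had a median of 0.21, with eater at 0.51. Lower were the testis list, in all 19 detected members, led by Mst98Cb (-0.39) and betaTub85D (-0.38; list median -0.30), and the accessory gland list, in 22 of 24 (median -0.18).

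These 8 lists were the only ones of 27 outside the range on the formaldehyde array, and the hemocyte list came inside it under 1 alternative. Alcohol and aldehyde oxidation genes had a median of 0.01, with 5 of 10 above 0, and the DNA damage response list one of 0.10, led by Corp (0.49) and Ku80 (-0.34). P450 genes (0.03), glutathione S-transferases (0.04), UDP-glycosyltransferases (0.02), efflux genes (0.02), heat shock proteins (-0.05), antioxidant enzymes (-0.01) and nutrient genes (0.07; InR, the insulin receptor gene, 0.81) also lay inside. The heat shock list held no Hsp70 gene, the aldehyde list neither Adh nor Aldh, and the DNA damage list neither rpr nor hid. Digestive enzymes had a median of 0.03 although LysX and Npc2e (2.43) passed 2-fold, cuticle proteins one of -0.01 and odorant binding proteins one of -0.10, with Obp69a at -0.87. Array control probe sets for actin and 18S ribosomal RNA were higher on this array than on the control array, by 0.76 and 0.50 log2 units in the median, whereas those for GAPDH and eIF-4a differed by 0.05 and -0.02.

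**Figure D2:**
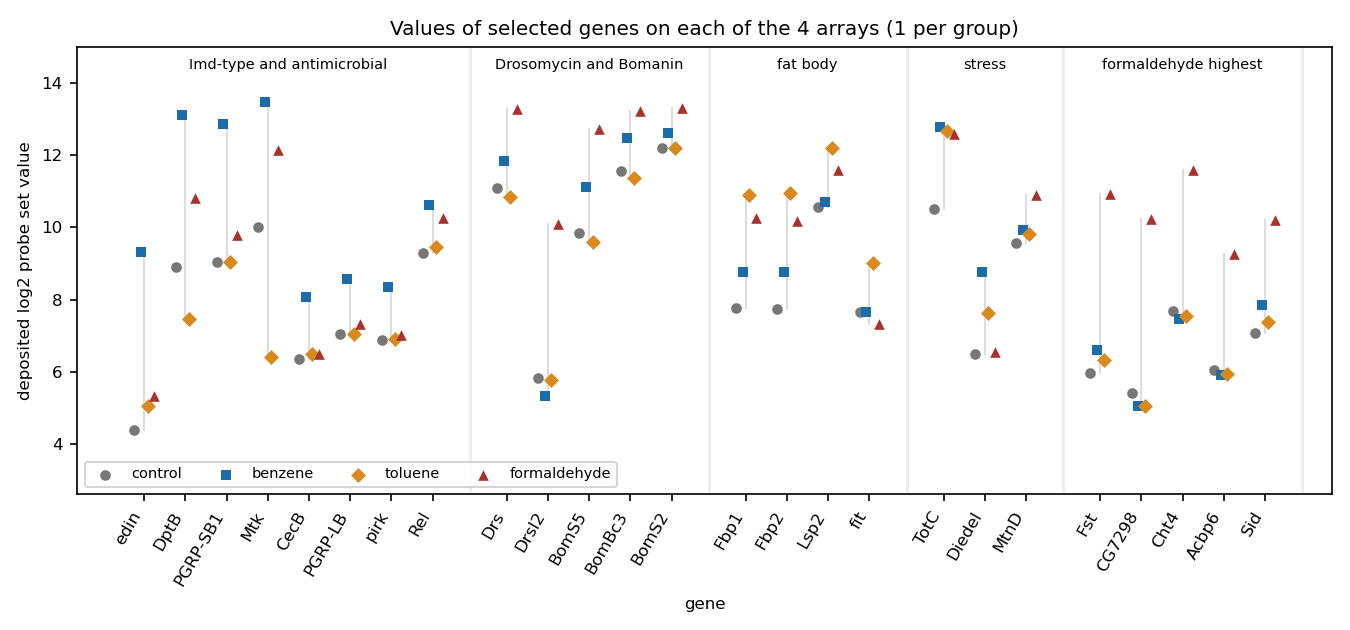
The y axis is the deposited log2 probe set value of each gene named on the x axis, with 1 symbol per array (1 array per group) and a grey line over their range. DptB, PGRP-SB1 and edin were highest on the benzene array, Drs and BomS5 on the formaldehyde array, and Fbp1 and Fbp2 on the toluene array, while TotC was lowest on the control array.

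Several lists lay inside the range for all 3 exposures. In the order benzene, toluene, formaldehyde, the medians were -0.11, -0.10 and 0.05 for neuron genes, 0.01, 0.01 and 0.01 for muscle genes, 0.09, 0.06 and 0.06 for Malpighian tubule genes, and -0.04, 0.01 and 0.09 for circadian genes. Cytosolic ribosomal protein genes were at -0.03, 0.02 and 0.01, and proteasome genes at -0.05, 0.02 and -0.08. The DNA damage list was at -0.06 for both benzene and toluene. Heat shock proteins (0.03), efflux genes (-0.03), antioxidant enzymes (0.01), nutrient genes (-0.03) and alcohol and aldehyde oxidation genes (-0.05) were inside for benzene, and odorant binding proteins (0.02) and photoreceptor genes (0.02) for toluene. Oxidative phosphorylation genes were at 0.02 for toluene and 0.03 for formaldehyde. Another 4 lists could not be ranked: of the Turandot genes TotC alone was detected, of the ovary and yolk genes Yp3 alone (0.02, 0.09 and 0.07), of the JNK and JAK/STAT targets puc (0.07, 0.14 and 0.34) and dome (-0.06, -0.04 and 0.32), and of the mitochondrial genome 0 genes were named on the array.

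**Figure D3:**
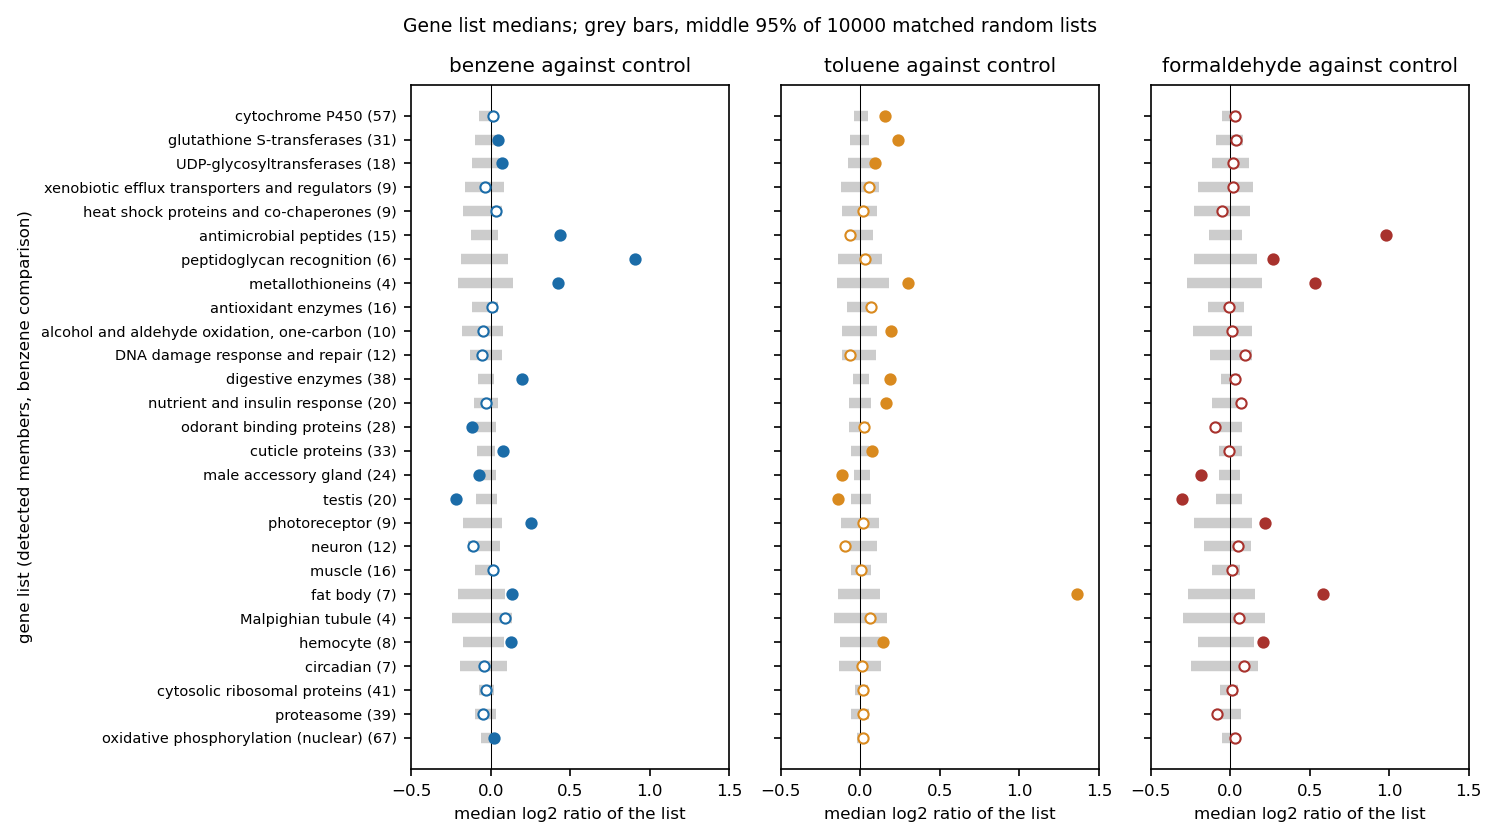
Points are median log2 ratios (x axis) of the detected members of each gene list (y axis) against the control, for 1 array per group; filled points lie outside and open points inside the grey bars, the middle 95% of 10000 matched random lists. Fat body genes for toluene (1.36), antimicrobial peptides for formaldehyde (0.98) and peptidoglycan recognition genes for benzene (0.91) stand farthest to the right, and the testis list lies left of its bar for each exposure.

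The genes to be named whatever their value were mostly close to the control. Formaldehyde dehydrogenase, encoded by Fdh, had log2 ratios of -0.06 (benzene), 0.05 (toluene) and 0.00 (formaldehyde). The abundant glutathione transferase gene GstD1 was at -0.09, 0.26 and 0.02, and the insecticide resistance gene Cyp6g1 at -0.10, 0.22 and -0.03. Cyp6a8 was at -0.08, 0.14 and -0.07. The heat shock gene Hsp68 was at -0.09, 0.02 and -0.05. The signs of Fdh and Cyp6g1 for formaldehyde and of Hsp68 for toluene flipped under another scaling. Cyp6a2 and the yolk protein gene Yp1 were below background on all 4 arrays. Drs was at 0.73 for benzene and -0.27 for toluene.

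Benzene and toluene, which differ by the methyl group, were compared directly at the same 24 h of exposure; the doses are not given in the sources used here. The largest single differences among named genes were in immune genes. Mtk was 135-fold lower on the toluene than on the benzene array, DptB had a log2 ratio of -5.64, edin was 19.4-fold and PGRP-SB1 14.1-fold lower. CecB, PGRP-LB, BomS5, pirk (a negative regulator of the Imd immune pathway), CG12057 and Rel (its NF-kB transcription factor) were between 2.22-fold and 3.01-fold lower. Higher with toluene were CG34040 (6.69-fold), Fbp2 (4.51-fold), Fbp1 (4.41-fold), CG15263 (3.54-fold), Cpr49Ac (3.52-fold), Lsp2 (2.82-fold), Obp99b (2.76-fold), mat (2.70-fold), fit (2.58-fold) and Npc2f (2.49-fold). Of 8126 detected genes 20 were at least 2-fold higher with toluene and 16 lower, and 98.3% lay within 0.5 log2 units. With 1 array each, no interval of any difference could be given.

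As groups, fat body genes were higher with toluene than with benzene (median 1.37, 5 of 7 above 0 and 2 below). The 4 past 2-fold were Fbp2, Fbp1, Lsp2 and fit. Higher with toluene as well were the 3 lists that follow. They were P450 genes (0.11, 44 of 58 above 0), glutathione S-transferases (0.21, 27 of 32) and nutrient genes (0.18, 18 of 21). Antimicrobial peptides (-0.26, 6 of 15 past 2-fold), peptidoglycan recognition genes (-0.50), photoreceptor genes (-0.21, 9 of 9 below 0) and digestive enzymes (-0.19) were lower. The testis list did not separate these arrays (0.07, inside the range). Metallothioneins were at -0.01, inside the range. In this comparison 18 of 27 lists lay outside the range, 10 of them under every alternative. The robust SD of the log2 ratios was 0.10 here, against 0.15 for each of these arrays and 0.21 for formaldehyde relative to the control. The plain SD, which the largest ratios sway, was 0.21 here, 0.22 for benzene, 0.19 for toluene and 0.31 for formaldehyde.

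Against the other exposures, formaldehyde again gave the larger counts. Relative to benzene 67 genes were at least 2-fold higher and 15 lower, and relative to toluene 65 were higher and 5 lower. Compared with each of the other 3 arrays, 49 genes were at least 2-fold higher on the formaldehyde array and 0 lower, of 8248 genes. On the benzene array the numbers were 10 and 3, and on the toluene array 4 (CG2444, Obp99b, Srr and fit) and 2 (Mtk and DptB). On the control array they were 0 and 2, the lower genes being Fbp2 and TotC; Srr was named after its values were seen.

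Only Fbp2 and TotC were at least 2-fold higher for all 3 exposures, and pairs of exposures shared more. Benzene and toluene shared 3 higher genes (with Diedel), where independent lists would share 0.05. Formaldehyde shared 10 of the 25 genes higher for benzene and 8 of the 19 higher for toluene. Independent lists would share 0.23 and 0.17. These counts cover genes detected in both comparisons of a pair. Simulated arrays set against 1 common control shared 6.33, 6.21 and 6.33 higher genes when their noise held all differences between the toluene and benzene arrays, and 0 when the 36 genes past 2-fold between those arrays were left out of it. The only lower gene shared was CG4830, by benzene and toluene. Across 8248 genes, which are not independent replicates, log2 ratios against the control had Pearson correlations of 0.51 (benzene and toluene), 0.56 (benzene and formaldehyde) and 0.51 (toluene and formaldehyde). Spearman's rho was 0.69, 0.68 and 0.68, and no rho was simulated to set beside it. Simulated arrays gave Pearson correlations of 0.49 for each pair with the first kind of noise and 0.50 with the second, through the shared control. The covariances were 0.0215, 0.0373 and 0.0302 against a simulated 0.0203 and 0.0104. The simulations gave the control array the same noise as the exposed arrays. The robust SD was 0.10 for toluene against benzene but 0.15 for each of them against the control. If the control array deviated more than the others, unchanged arrays would correlate above the simulated values. The simulations therefore do not set the level expected without an effect. The 1 control array could not be split, so part or all of any excess may come from it.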

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

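All tests in this part were chosen after the results were seen.

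DptB and Mtk went in opposite directions past 2-fold between exposures. DptB was at 8.92 on the control array, 13.10 with benzene, 7.46 with toluene and 10.82 with formaldehyde. Its log2 ratio was 5.64 higher for benzene than for toluene and 3.36 higher for formaldehyde than for toluene. For Mtk, at 10.02 on the control array, those differences were 7.08 and 5.72. The differences were not tested, since each group has 1 array.

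The first pattern weighed is the immune genes on the benzene array. Scaling between arrays by level, which would move genes of the same level alike, is argued against: the antimicrobial peptide list had a median of 0.44, where random lists matched on level had -0.12 to 0.05. These values are part of the pattern itself. The list also stayed outside the range under quantile, cyclic loess and median scaling. A larger share of fat body or hemocyte RNA was not decided. The highest of the 15 detected markers were Fbp2 (1.03), Fbp1 (0.99) and Mtp (0.72), with a median of 0.13 over all. The 7 antimicrobial peptide and peptidoglycan recognition genes past 2-fold had a median of 1.73, but they were kept for passing 2-fold. Over all detected members the antimicrobial peptide list had a median of 0.44 and the peptidoglycan recognition list 0.91. Both lay above the marker median of 0.13 and below Fbp2, the highest single marker. What stays open is such a share, an effect of benzene, and microbes or other conditions of 1 fly pool. The effect of benzene and the pool cannot be told apart, because there was 1 array per group.

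The second pattern is the 88 genes higher on the formaldehyde array. Array noise is argued against for the antimicrobial peptide genes among them: 8 of the 16 detected members of that list, which was fixed beforehand, were at least 2-fold higher, where an even spread of the 88 genes would give 0.17. Symmetric array noise had no separate test for the other genes as a set, but the asymmetry that made the pattern is itself unlike such noise. Of all detected genes outside that list, 46 were at least 2-fold above each of the other 3 arrays and 0 below. Among genes bright enough on those arrays to be seen 2-fold lower, the numbers were 26 and 0. A one-sided deviation of this array stays open. RNA degradation stays open too, because the excess of 3' over 5' signal did not go one way: it was 0.95 for GAPDH, inside the 0.93 to 1.00 of the other 3 arrays, 1.63 for eIF-4a, above their 1.51 to 1.59, and 0.83 for actin, below their 1.09 to 1.16. So do conditions of 1 fly pool other than formaldehyde, which cannot be told apart from formaldehyde itself with 1 array per group.

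The third pattern is the lower testis list on all 3 exposed arrays. Scaling by level is argued against: the medians of -0.22, -0.14 and -0.30 lay below those of random lists matched on level, whose lower limits were -0.09, -0.06 and -0.09. These are the values that showed the pattern. The testis list also stayed outside the range for each exposure under quantile, cyclic loess and median scaling. A deviation of the control array alone is argued against as the whole cause, because the list was also lower for formaldehyde than for toluene (-0.15, outside the range). Whether the control array held a larger testis share of RNA cannot be told apart from lower expression within the testis or an effect of the vapours. The shift was not confined to the testis list. The accessory gland list was also below the range on all 3 exposed arrays (medians -0.08, -0.12 and -0.18), although for benzene this was lost under some alternatives. Testis-type copies of proteasome, ribosome and mitochondrial genes had medians of -0.25, -0.17 and -0.29 for benzene, toluene and formaldehyde, but this set was made after such copies were seen among the lowest members of 3 other lists, so it decides nothing.

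Probe sets without a single named gene also held signals above the control. Of 5123 such probe sets, 1025 (benzene), 1015 (toluene) and 1016 (formaldehyde) were detected. Among these 13, 9 and 27 were at least 2-fold higher and 0, 3 and 1 lower. As deposited, the largest log2 ratios, 5.81 and 5.23 for benzene and 5.67 for formaldehyde, exceeded those of every named gene on these arrays. The 5.81 and 5.67 came from control values of 3.73 and 4.83, below the control array's background of 4.88. Neither ratio was taken against the background, so their size is uncertain. The probe set at 5.23 for benzene was at -2.14 for toluene. Control probe sets for 18S ribosomal RNA were 0.50 log2 units higher on the formaldehyde than on the control array, and those for actin 0.76.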

How the results depend on the processing

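No paired analysis was possible because the groups share only replicate number 1 and no result comes from a test. The size threshold moved every count. At 1.5-fold the totals were 110 (benzene), 95 (toluene) and 236 (formaldehyde) against the control, 108 for toluene against benzene, and 186 and 178 for formaldehyde against benzene and toluene. At 3-fold they were 9, 7, 37, 10, 31 and 30. Genes standing apart from the other 3 arrays numbered 20 (control), 26, 21 and 102 at 1.5-fold, and 1, 5, 1 and 20 at 3-fold. By construction a lower threshold takes in more genes. With the dim filter at the 75th percentile, which leaves fewer genes, the toluene total of 23 became 15; with all non-control probe sets counted, an alternative chosen after seeing the data, it became 35. The remaining alternatives kept each total, and each correlation between exposures, within 1.5 times.

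With the mean of the other 2 exposed arrays in place of the control, the totals were 34, 32 and 66 against 35, 23 and 91. The share of higher genes went from 77.1% to 35.3% for benzene and from 87.0% to 34.4% for toluene, and was 93.9% for formaldehyde. For benzene and toluene this reference held the formaldehyde array. That array had 67 genes at least 2-fold above benzene and 15 below, and 65 above toluene and 5 below, which draws calls to the lower side. How much of the change this made was not tested. Scaling moved no share by over 10 percentage points, and no median over all genes by 0.1 log2 units. Of 403 named values at most 3 changed sign under a scaling, none larger than 0.03.

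Of the lists outside the random range, 8 of 14 (benzene), 8 of 12 (toluene), 7 of 8 (formaldehyde) and 10 of 18 (toluene against benzene) stayed outside under every alternative. Medians that changed sign were glutathione S-transferases for benzene at the 75th percentile filter (-0.016), nuclear oxidative phosphorylation for benzene under quantile scaling (-0.003) and for toluene against benzene under cyclic loess (-0.018) and median centring (-0.002), and cuticle proteins for toluene with no filter (-0.011) and for toluene against benzene at the 75th percentile (0.014). The cause was not tested. Pseudocount alternatives were not run, since the values are already log2. Dim probe sets limit the ratios: backgrounds were 4.64 to 4.88, and compressed values below them bound a fold from one side.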

Other observations

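All tests in this part, and the septate junction and pathway target lists it uses, were chosen after the results were seen.

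Genes of the smooth septate junction, the barrier between cells of the fly midgut and Malpighian tubules, were higher together on the formaldehyde array. Tsp2A was 2.90-fold higher than on the control array, Ssk 2.79-fold, mesh 2.57-fold and hoka 2.25-fold, 4 of 4 genes, with a median log2 ratio of 1.42. A second probe set of mesh lay below background on all 4 arrays. On the benzene and toluene arrays the median of these genes was 0.02 and 0.05. The hypothesis that septate junction genes were higher in general is argued against by the 17 genes of pleated septate junctions, found in other epithelia, whose median for formaldehyde was 0.058. The lists fixed for tissues with smooth junctions did not stand apart on this array: digestive enzymes had a median of 0.03, with 20 of 39 above 0, and Malpighian tubule genes one of 0.06, with 2 of 4 above 0.

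Targets of both main immune pathways were higher on the benzene and the formaldehyde arrays, to different degrees. Targets of the Imd pathway, which responds to Gram-negative bacteria, had a median log2 ratio of 1.63 for benzene, with 8 of 8 detected genes past 2-fold. For formaldehyde it was 0.28, with 7 of 7 above 0, DptB 3.73-fold and Rel 1.95-fold higher. Targets of the Toll pathway, which responds to fungi and Gram-positive bacteria, had a median of 0.44 for benzene, with 13 of 13 above 0 and 1 past 2-fold, and of 1.11 for formaldehyde, with 8 of 13 past 2-fold. Between the 2 arrays, formaldehyde against benzene, 13 of 13 Toll targets were above 0 (median 0.75) and 0 of 8 Imd targets (median -1.47). Both target lists were made with the values in view, so these counts decide nothing. Detected immune peptide genes in neither list included BomS6 (0.43), BomS4 (0.28) and Def (-0.58), formaldehyde against benzene. A single immune gene program at 2 strengths is argued against by the immune lists, whose members, but not the rule used, were fixed beforehand. Of their 16 genes above the control on both arrays, 2 (BomS5 and Drs) were at least 2-fold higher with formaldehyde than with benzene. Another 5 (PGRP-SB1, DptB, CecB, Mtk and PGRP-LB) were at least 2-fold lower. The rule, set after the values were seen, asked for at least 2 each way and was met at that minimum. Over all 22 detected genes the numbers were 3 and 5. Whether the exposure or the pool of flies differed in its immune state stays open.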
